A study of Mus musculus with 6 samples.

How the data were processed

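RNA of 6 mouse liver samples was sequenced, 3 of the Ctrl group and 3 of the IRF3-2D group, from libraries made with poly-A selection and a strand-specific kit, per the labels' protocols. Groups and replicate numbers were taken from the sample titles, and each column of the table was matched to its sample by the library name in the labels. The values are deposited estimated counts per gene, 1 column per library, not normalized. Salmon 1.2.1 and the builds GRCm38 and mm10 are named in the submitters' processing notes without a role, and the annotation, the summing of transcripts to genes, the strand setting and any filter are not given in the sources used here. Salmon assigns reads to transcripts by estimation, yet every deposited value was a whole number, so the values were treated as rounded estimates and used as they stand. The labels number the replicates without saying that each came from a separate mouse, so p-values measure the spread between these samples, which may be technical.

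The table had 20894 gene identifiers, of which 20817 were matched to a symbol in GENCODE M21 (GRCm38), and 20769 were protein-coding there. The other 77 are not in that release, so the annotation behind the table may be a later one, and coordinates are those of GENCODE M21 on GRCm38. Rows without a symbol held at most 0.022% of a library's counts and were kept under their identifier. Of the rows, 5285 had no count in any library. Some genes that every cell uses were listed near 0, so the counts may cover only part of a gene's transcripts or lack reads shared with other genes, and fold changes may then describe part of a gene's output. Of 1103 tested genes with 1 annotated transcript, where this cannot arise from a choice among transcripts, 181 were higher and 169 lower, 31.7% called against 25.7% of the other genes. Genes with no row in the table were not analysed here.

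Depth was 12054096 to 14830629 counts per library, with 10333 to 10846 genes at 10 or more counts. A count of 0 allows up to 0.202 to 0.249 CPM at 3 counts in a library, for counting error only. The 20 most abundant genes held 34.3% ± 1.20 of the counts in Ctrl and 23.6% ± 1.00 in IRF3-2D libraries (SD, n = 3 each). Alb held 10.2% ± 2.27 and 5.93% ± 0.283, and mitochondrially encoded genes held 11.7% ± 0.281 and 8.26% ± 0.481. TMM factors were 0.822 to 0.879 in Ctrl and 1.12 to 1.23 in IRF3-2D. No 2 libraries of a group agreed within sampling noise: the chi-square per degree of freedom between replicates was 21.7 to 132.

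Genes were kept by filterByExpr of edgeR 4.0.16 at its defaults (R 4.3.3), which left 10802. IRF3-2D was compared with Ctrl by edgeR's quasi-likelihood F-test with TMM scaling and the group as the only term, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Levels are CPM with TMM, and standard errors of log2 fold changes come from the log2 fold change and its F statistic. Where all libraries of a group were at 0, the fold is a lower bound against 3 counts in each of its libraries. The test was tried on simulated counts with 200 changed genes among 10734 tested: it recovered 46.9% of genes changed 2-fold and 78.3% of those changed 4-fold, 7.8% of its calls were false, and it called 0 genes when none was changed. Apart from the changed genes, the simulated groups had the same mean profile. Far fewer genes changed than were called in the data, so these rates need not hold there and the scaling was not tried.

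Before the data were examined, 46 gene lists with 988 distinct genes were written from textbook knowledge of liver, interferon, ethanol and cell type genes, and 942 of these genes had a row. Some genes stand in more than 1 list, so the lists are not independent. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, then with an estimated correlation and with fry, adjusting over 40 lists. Camera called 21 lists, 5 up and 16 down. With an estimated correlation the call of 1 list held, that of class I antigen presentation, and fry, which asks whether a list's genes move on balance in 1 direction, called 17. Named genes were fixed by rule: Irf3, Fgf21 and Polr2g; the 10 largest rises and the 10 largest falls among called genes with a mean log2 CPM of at least 1 and no overlap between groups, without predicted genes; and from each list the 4 called members with the smallest adjusted p, or, in a list with no call, the member with the smallest p as a value only, with names left out where a paragraph would hold too many. Genes named outside the rule are said to be so, apart from Fgfr1 and Fgfr2, named as the remaining tested members of their list after their values were seen.

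The share of each named or listed gene's 31-base words that also occur in transcripts of another gene was computed from GENCODE M21, to mark genes whose reads cannot be placed with certainty. Alternatives fixed beforehand were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, library totals alone, no filter, a mean count of at least 50, each library left out, the replicate number as a block, glmTreat at a fold of 1.2, a robust fit, library sizes without the 20 most abundant genes, and camera without interferon-stimulated genes in the other lists. A fit on genes with 1 annotated transcript was added after the data were seen.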

Results

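Liver of mice carrying a Cre-dependent IRF3-2D allele was profiled by RNA sequencing after a single dose of ethanol. IRF3 is a transcription factor of the antiviral response, and the 2D allele is made to express a constitutively active form of it once Cre removes a stop cassette. In the IRF3-2D group Cre was delivered with an adeno-associated virus under the TBG promoter, which is active in hepatocytes, and the Ctrl group received the same vector with GFP. Each group held 3 liver samples, collected 2 h after 3 g/kg of ethanol, so both groups were exposed to ethanol and the series offers a single comparison. The table held estimated counts for 20894 genes, with totals of 13940893 to 14830629 per library in Ctrl and 12054096 to 13606973 in IRF3-2D. Some genes that every cell uses stood near 0 in all libraries, so a listed value may cover only part of a gene's transcripts.

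The comparison of IRF3-2D with Ctrl liver asks what active IRF3 in hepatocytes does to the liver transcriptome, with Fgf21 and Polr2g named by the series itself. The groups also differ in Cre against GFP, and the series has no group with Cre and without the allele. Effects of Cre or GFP therefore cannot be told apart from those of active IRF3 in any result below. Of 39 interferon-stimulated genes 34 were called higher in IRF3-2D liver, among them Rsad2 at 201-fold and Ifit1 at 81.8-fold, and all 18 antigen presentation genes were. With an estimated correlation only the antigen presentation list kept its call (adjusted p = 0.0271, against 0.27 for the interferon-stimulated list). Fgf21, which encodes a hormone secreted by the liver in metabolic stress, fell 11.1-fold, and Polr2g, which encodes a subunit of RNA polymerase II, rose 6.41-fold. Called lower were 12 of 21 genes of fatty acid and triglyceride synthesis, 23 of 44 PPARalpha targets and genes of fatty acid oxidation (5 were higher), 10 of 20 pericentral genes (1 was higher) and all 13 mitochondrially encoded genes. None of these 4 lists was called with an estimated correlation (adjusted p = 0.27, 0.337, 0.542 and 0.27). With edgeR's quasi-likelihood test 1426 genes were higher and 1418 lower at a Benjamini-Hochberg adjusted p under 0.05, of 10802 tested, and 533 and 523 of these changed more than 2-fold. The first principal component held 51.9% of the variance and separated the groups, and 44.9% of the tested genes had no overlap between the groups' values, where chance gives 10%.

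Irf3 itself, the gene that the allele carries, checked the labels. Irf3 (ENSMUSG00000003184, chromosome 7, 44997648 to 45002848, plus strand in GENCODE M21 on GRCm38) stood at 49.7 ± 9.34 CPM (TMM scaled) in Ctrl and 120 ± 15.3 in IRF3-2D liver (SD, n = 3 each). That is a log2 fold change of 1.27 (SE 0.16, adjusted p = 0.0015 by edgeR), with all 3 IRF3-2D libraries above all 3 Ctrl libraries. The counts do not separate the allele's transcript from that of the native gene.

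Fgf21 (ENSMUSG00000030827, chromosome 7, 45613886 to 45615490, minus strand), a gene with 1 annotated transcript, had 85, 91 and 90 counts in the Ctrl libraries and 1, 14 and 14 in the IRF3-2D libraries. Its level was 7.20 ± 0.387 CPM in Ctrl and 0.643 ± 0.501 in IRF3-2D (SD, n = 3 each), a log2 fold change of -3.47 (SE 0.68, adjusted p = 0.010 by edgeR). Polr2g (ENSMUSG00000071662, chromosome 19, 8793127 to 8798577, minus strand) rose from 11.5 ± 0.588 to 73.8 ± 14.4 CPM (SD, n = 3 each), a log2 fold change of 2.68 (SE 0.16, adjusted p = 8.7e-05 by edgeR). Polr2g has 4 annotated transcripts, so its rise may describe only part of the gene's output. Of 13 subunit genes of RNA polymerase II, 11 were tested. Polr2a and Polr2j, named after their values were seen, had mean counts of 4.5 and 2.33 and did not pass the filter. Of the 11 tested, 4 were called higher and none lower, and 6 were higher and 1 lower when adjusted over the list alone. With library totals alone 8 were higher. Polr2d rose 1.91-fold, while the calls of Polr2e (1.31-fold) and Polr2k (1.39-fold, with 27.3% of its sequence words shared with other genes) did not hold when single libraries were left out. The call of Polr2e was lost without Ctrl replicate 2 (log2 fold change 0.36) or any of the 3 IRF3-2D libraries (0.37 to 0.40), and that of Polr2k without any 1 of the 6 libraries (0.39 to 0.54). Both were lost with the replicate block. As a list, the subunits did not stand apart from other genes (camera adjusted p = 0.139), while fry called them up (adjusted p = 0.00213). The FGF21 receptor complex list has 6 members, of which 5 had a row and 4 were tested. Of these 4, Fgfr4 fell 7.45-fold and Fgfr3 fell 2.85-fold, while Fgfr1 and Fgfr2 were not called, also when adjusted over the list alone. With library totals alone, however, 1 of the 4 was higher and 2 were lower.

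**Figure D1:**
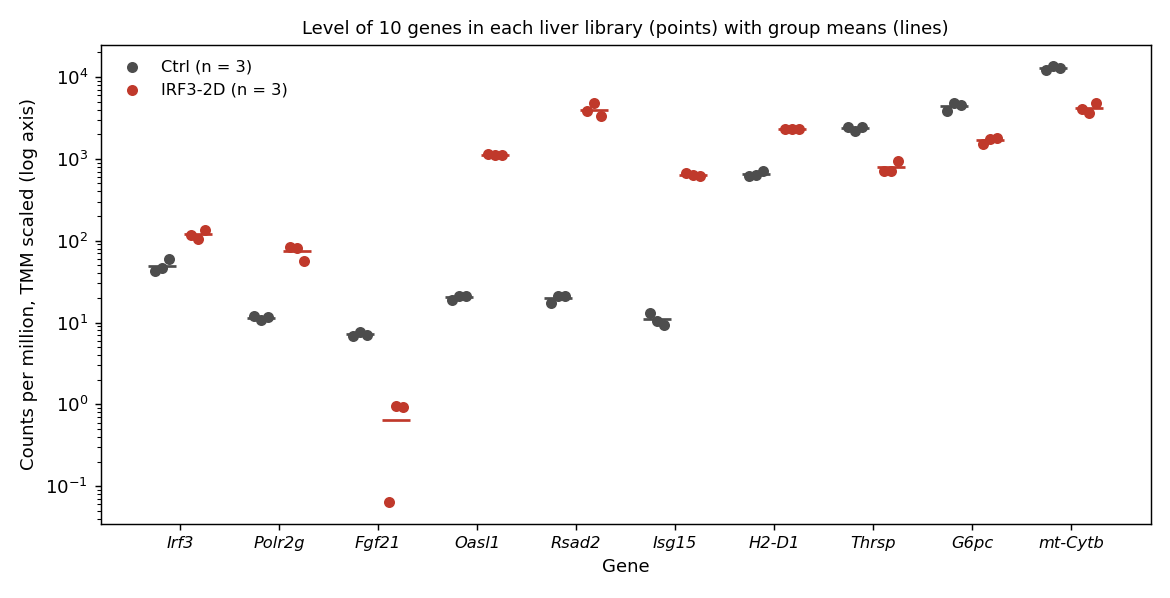
CPM with TMM scaling on a log axis for 10 genes, with a point for each library and a line at each group's mean (Ctrl n = 3, IRF3-2D n = 3). Fgf21 lies at 7.20 in Ctrl and 0.643 in IRF3-2D liver on average, Polr2g at 11.5 and 73.8, and Rsad2 at 19.8 and 3983, with no overlap between groups in any of the 10 genes.

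Interferon-stimulated genes had the largest median change of the 40 lists tested. Of 39 tested members, 34 were called higher and none lower (36 higher when adjusted over the list alone), with a median log2 fold change of 2.06 (camera adjusted p = 9.35e-24, and adjusted p = 0.27 with an estimated correlation). Rsad2, an antiviral enzyme, rose from 19.8 ± 2.22 to 3983 ± 713 CPM (SD, n = 3 each), and Oasl1 rose 55.1-fold. Ifit1, whose product binds foreign RNA, rose 81.8-fold, and the ubiquitin-like modifier Isg15 rose 58.5-fold. Both of these have 1 annotated transcript and share 10.5% and 12.8% of their sequence words with other genes. All 18 genes of class I antigen presentation rose, also when adjusted over the list alone, with a median log2 fold change of 1.44 (camera adjusted p = 2.8e-17, and adjusted p = 0.0271 with an estimated correlation). Psmb8, a subunit of the immunoproteasome, rose 4.02-fold. H2-Q6 (5.29-fold), H2-D1 (3.59-fold) and H2-T22 (3.49-fold) share 26.7% to 51.0% of their sequence words with related genes, so how the reads fell among them is uncertain. No gene of the 19 type I and III interferons in the table reached the count filter, and the highest count of any of them in a library was 3. Among 14 tested NF-kappaB targets and chemokines, Irf1 rose 2.00-fold and Cxcl1 fell 7.55-fold, a call that was lost with limma-voom, without Ctrl replicate 3 (log2 fold change -2.05) and without IRF3-2D replicate 1 or 2 (-2.67 and -2.75). Both counts were the same when adjusted over the list alone, and the list was not called (camera adjusted p = 0.618).

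Markers of other liver cells moved beside these groups. Of 16 tested Kupffer cell and macrophage markers, 5 were called higher and none lower (9 higher when adjusted over the list alone), with Mpeg1 up 4.14-fold and the complement gene C1qb up 1.62-fold (camera adjusted p = 0.00417, and adjusted p = 0.592 with an estimated correlation). With library totals alone 13 were higher, and the list was not called against other genes (adjusted p = 0.0604). Fry called neither this list (adjusted p = 0.07) nor that of the endothelial markers (0.074). Among the called macrophage markers, Cd5l lost its call without any 1 library other than IRF3-2D replicate 3. Cybb lost its call without Ctrl replicate 2 or 3 and without IRF3-2D replicate 1 or 2. Of 17 endothelial markers, 5 were called lower and none higher (5 lower when adjusted over the list alone), Ehd3 at 1.67-fold among them (camera adjusted p = 0.00434, and adjusted p = 0.592 with an estimated correlation). With library totals alone their median log2 fold change of -0.41 became 0.04, none was called lower (Ehd3 included), 1 was higher and the list was not called (adjusted p = 0.0604). Among the called endothelial markers, Oit3 lost its call without Ctrl replicate 1, 2 or 3 or IRF3-2D replicate 1. Ptprb lost its call without Ctrl replicate 2 or 3 or IRF3-2D replicate 2 or 3, and Tie1 without IRF3-2D replicate 2 or 3. Of 8 monocyte and dendritic cell markers 1 was called, Ly6c2 (8.21-fold higher, with 23.7% of its words shared with other genes, lost with limma-voom, with the replicate block and without IRF3-2D replicate 2, where its log2 fold change was 2.59), and the list was not called (camera adjusted p = 0.349, but 0.0396 without IRF3-2D replicate 3). Of 9 T and NK cell markers 1 was called, the chemokine Ccl5 (7.52-fold higher; camera adjusted p = 0.201), and of 16 stellate cell markers 1, Reln (1.64-fold lower, lost with library totals alone, where 3 markers were higher; camera adjusted p = 0.406). These counts were the same when adjusted over each list alone. Among the 7 cholangiocyte, 6 erythroid, 4 B cell and 3 neutrophil markers tested, edgeR and limma-voom called 0, DESeq2 called 1 (the cholangiocyte marker Spp1, 3.22-fold higher with edgeR, with 14.3% of its words shared) and 2 cholangiocyte markers passed an unadjusted p of 0.05 (camera adjusted p = 0.95 for the cholangiocyte and 0.642 for the erythroid list). Of all these, 4 were higher with library totals alone, 2 without IRF3-2D replicate 3, and 1 each with the replicate block, with a mean count of at least 50 and without Ctrl replicate 1 or 2.

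The lists of fatty acid synthesis and of fatty acid oxidation were called lower by camera. Of 21 tested genes of fatty acid and triglyceride synthesis, 12 were called lower and none higher (16 lower and 1 higher when adjusted over the list alone), with a median log2 fold change of -1.01 (camera adjusted p = 1.96e-08, and adjusted p = 0.27 with an estimated correlation). Thrsp, a regulator of lipogenesis, fell 3.01-fold from 2378 ± 153 to 791 ± 135 CPM (SD, n = 3 each). Gpat4 (2.69-fold) and Dgat2 (2.55-fold), enzymes of triglyceride assembly, and Elovl6 (2.54-fold), a fatty acid elongase, were lower too. Of 44 PPARalpha targets and genes of fatty acid oxidation, 23 were called lower and 5 higher (26 and 5 when adjusted over the list alone; camera adjusted p = 8.3e-08, and adjusted p = 0.337 with an estimated correlation). Ppara, which encodes the nuclear receptor itself, fell 2.62-fold. The acyl-CoA thioesterases Acot1 and Acot4 fell 11.3-fold and 4.62-fold. Acot1 shares 22.7% of its sequence words with other genes, so its counts are uncertain.

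Genes of glucose and amino acid metabolism and glucocorticoid-responsive genes were also more often called lower than higher. Of 28 tested genes of gluconeogenesis, glycogen and glycolysis, 10 were called lower and 3 higher (10 and 5 when adjusted over the list alone; camera adjusted p = 0.0101, and adjusted p = 0.414 with an estimated correlation). G6pc, the last enzyme of glucose release, fell 2.59-fold from 4390 ± 481 to 1693 ± 157 CPM (SD, n = 3 each), and the glycogen genes Gys2 and Ppp1r3c fell 2.09-fold and 4.07-fold. Of 39 genes of amino acid catabolism and the urea cycle, 16 were called lower and 1 higher (21 and 2 when adjusted over the list alone; camera adjusted p = 2.38e-06, and adjusted p = 0.41 with an estimated correlation). Hal, which degrades histidine, fell 3.03-fold, and the urea cycle gene Ass1, which shares 43.1% of its sequence words with other genes, fell 2.91-fold. The medians of both lists, -0.37 and -0.34 on the log2 scale, turned to 0.08 and 0.10 with library totals alone, where 9 were higher and 8 lower of the first list and 4 and 4 of the second. The median of all tested genes was then 0.49, and camera still called both lists down (adjusted p = 0.00726 and 0.00107). Of 16 glucocorticoid-responsive genes 8 were called lower and none higher (10 lower when adjusted over the list alone), among them Errfi1 (2.52-fold) and Tat (3.47-fold), with camera adjusted p = 0.000215, and adjusted p = 0.27 with an estimated correlation.

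Lists of hepatocyte markers and of pericentral genes were called lower by camera, and that of periportal genes was not called. Of 18 hepatocyte markers, 10 were called lower and 3 higher (11 and 3 when adjusted over the list alone; camera adjusted p = 0.00123, and adjusted p = 0.41 with an estimated correlation). Their median log2 fold change of -0.42 was 0.03 with library totals alone, where 4 were higher and 5 lower. Camera still called the hepatocyte list down there (adjusted p = 0.00264). Of 20 pericentral genes, 10 were called lower and 1 higher (12 and 1 when adjusted over the list alone; camera adjusted p = 0.000148, and adjusted p = 0.542 with an estimated correlation and 0.0516 with fry). The glutamate transporter Slc1a2 fell 9.79-fold and Oat, an enzyme of ornithine metabolism, fell 5.63-fold. Of 21 periportal genes, 6 were called lower and 3 higher (7 and 3 when adjusted over the list alone), and that list was not called (camera adjusted p = 0.132). With library totals alone 5 were higher and 4 lower. All 13 mitochondrially encoded genes were lower, also when adjusted over the list alone, with a median log2 fold change of -1.13 (camera adjusted p = 1.44e-11, and adjusted p = 0.27 with an estimated correlation), and mt-Cytb fell 3.10-fold. These genes share from 0% to 100% of their sequence words with other genes (6.55% for mt-Cytb), so the placement of reads is uncertain for some of them. Of 46 cytosolic ribosomal protein genes 24 were called lower and none higher (27 lower and 1 higher when adjusted over the list alone; camera adjusted p = 1.31e-08, and adjusted p = 0.27 with an estimated correlation). Their median of -0.37 became 0.09 with library totals alone, where 5 were higher and 1 lower. Camera still called the ribosomal protein list down there (adjusted p = 0.012). Rpl22 fell 1.86-fold and Rpsa fell 1.51-fold, and the call of Rpsa, with 31.01% of its words shared with other genes, was lost with library totals alone. Of 47 nuclear genes of oxidative phosphorylation 12 were called lower and none higher (12 lower when adjusted over the list alone; camera adjusted p = 0.000148, and adjusted p = 0.592 with an estimated correlation and 0.0762 with fry). Their median of -0.20 became 0.25 with library totals alone, where 20 were higher, none was lower and the list was no longer called (adjusted p = 0.691).

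**Figure D2:**
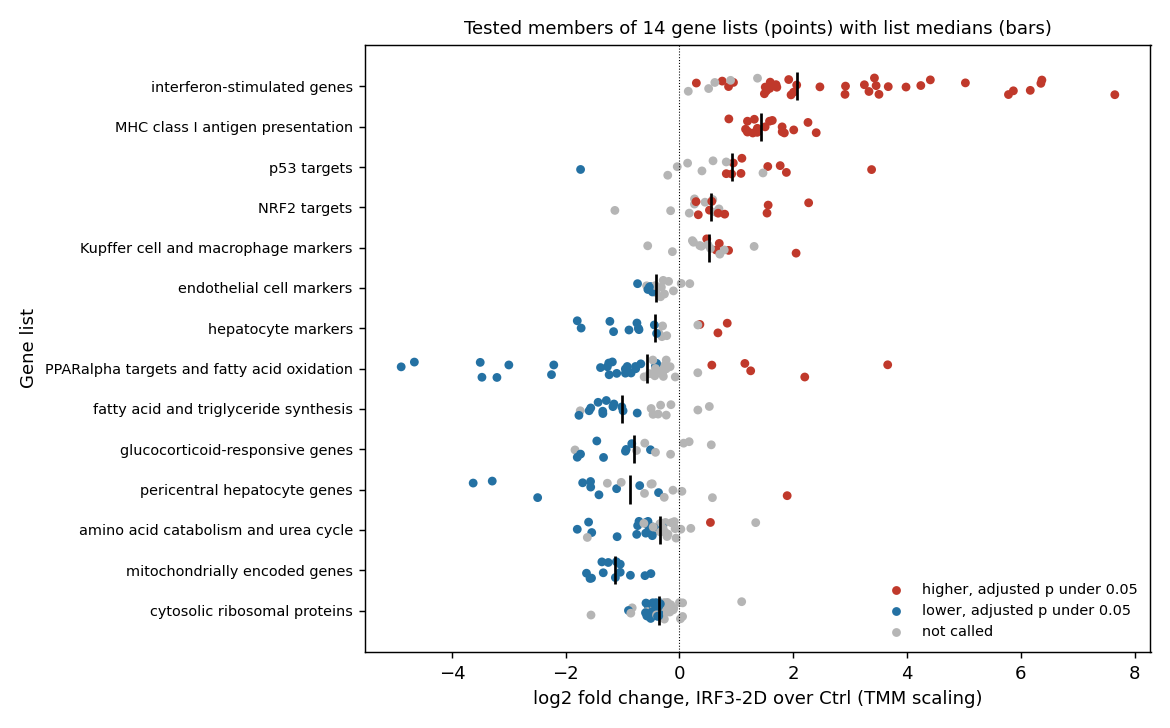
The log2 fold change of IRF3-2D over Ctrl liver with TMM scaling for each tested member of 14 gene lists, coloured by its call with edgeR, with a bar at each list's median. The interferon-stimulated genes lie around a median of 2.06 and the 13 mitochondrially encoded genes around -1.13, and with library totals alone the medians of the endothelial, hepatocyte, amino acid and ribosomal protein lists lie above 0. The median of all tested genes is then 0.49.

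Genes of stress responses and of ethanol metabolism changed in different directions. Of 18 NRF2 targets, 9 were called higher and none lower (10 higher when adjusted over the list alone; camera adjusted p = 0.00021, and adjusted p = 0.324 with an estimated correlation), including the antioxidant enzyme gene Srxn1 (2.95-fold) and Osgin1 (2.91-fold). Of 17 p53 targets, 9 were called higher and 1 lower (9 and 1 when adjusted over the list alone), with Eda2r up 10.4-fold, Ccng1 up 1.93-fold and Perp down 3.34-fold (camera adjusted p = 0.00417, adjusted p = 0.414 with an estimated correlation and 0.113 with library totals alone). Of 17 genes of the unfolded protein response, 4 were called lower and none higher (5 lower when adjusted over the list alone), Herpud1 (1.92-fold) and Sel1l (2.30-fold) among them (camera adjusted p = 0.000425, and adjusted p = 0.271 with an estimated correlation). Their median of -0.30 became 0.17 with library totals alone, where 2 were higher and 3 lower. Camera still called the list down there (adjusted p = 0.016). Of 14 genes of ethanol and acetaldehyde metabolism, 3 were called higher and 4 lower (3 and 5 when adjusted over the list alone, 5 and 3 with library totals alone), and the list was not called (camera adjusted p = 0.618). Adh1, which oxidises ethanol in hepatocytes, rose 1.57-fold, and Cat, which encodes catalase, fell 1.73-fold.

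The largest single changes, among called genes past the level set by the naming rule, were not limited to the interferon-stimulated genes. Slc1a1, a glutamate transporter gene, was listed at 0 in all 3 Ctrl libraries and at 381 ± 19.0 CPM in IRF3-2D (SD, n = 3), at least 1565-fold higher when set against 3 counts per library. Fam19a4, Hr, Gbp9, Zfp518b, Smc4, Cacna2d3, Rapgef4 and Abcc4 were also listed at 0 in all Ctrl libraries. They were at least 17.4-fold to 72.1-fold higher, with levels of 4.24 to 17.6 CPM, and Gbp9 shares 18.3% of its words with other genes. The counts may cover only part of a gene's transcripts, so a listed 0 does not show that the whole gene was silent. The folds of Slc1a1 and of these genes may then describe part of each gene's output. Apart from that of Slc1a1, these lower bounds lie below the folds of Rsad2 and Ifit1 given above. Among the largest falls were those of Mup19, Mup17 and Mup15, major urinary protein genes (772-fold, 316-fold and 104-fold), which share 86.2% to 100% of their sequence words with other genes, so their separate values are uncertain. All Mup genes summed held 8.04% ± 3.99 of the counts in Ctrl and 3.66% ± 0.773 in IRF3-2D libraries (SD, n = 3 each, without TMM), and the groups overlapped (4.07% to 12.0% and 2.78% to 4.21%). The separate folds lean on Ctrl replicate 2, without which the log2 fold changes of Mup19, Mup17 and Mup15 went from -9.59, -8.31 and -6.70 to -8.87, -6.19 and -5.11. The call of Mup15 was lost without IRF3-2D replicate 2 (log2 fold change -6.17) or 3 (-6.47) and with the replicate block (-6.34). The organic anion transporter gene Slc22a7 fell 119-fold, Extl1 fell 73.3-fold, Mmd2 fell 51.0-fold (log2 fold change -5.67, and -4.81 without Ctrl replicate 1) and Lad1 fell 36.0-fold. Cyp2c40, Cyp2c69 and Slc22a28, members of multigene families, fell 61.3-fold, 38.5-fold and 38.2-fold, and their separate values are uncertain too. With limma-voom the calls of Smc4, Mup17, Mup15, Slc22a7, Extl1 and Mmd2 were lost.

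Changes are relative to TMM scaling, which puts the median of the tested genes at a log2 fold change of 0.03; library totals alone shifted that median by 0.45, and 88.7% of the called genes were then higher (4497 higher and 571 lower) against 50.1% with TMM. Without IRF3-2D replicate 1 the numbers called were 866 higher and 956 lower, and without IRF3-2D replicate 2 they were 851 and 926.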

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

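The fit on genes with 1 annotated transcript was chosen after seeing the data; all other alternatives were planned. The log2 fold changes of Irf3, Fgf21 and Polr2g kept their direction and their call in every alternative that tested them. Without 1 library they ranged from 1.16 to 1.43 for Irf3, from -3.85 to -2.94 for Fgf21 and from 2.57 to 2.82 for Polr2g. Fgf21 was not tested with a mean count of at least 50, and Irf3 and Polr2g, with several transcripts, were not tested among genes with 1. Leaving out 1 library gave 851 to 1312 genes higher, 926 to 1363 lower and 18 to 23 lists called, with fewer samples in each fit. Library totals alone gave 4497 genes higher and 571 lower, which follows from the TMM factors it drops, and glmTreat at a fold of 1.2 gave 864 higher and 918 lower, which follows from its stricter null. Genes with 1 transcript gave 203 higher, 188 lower and 3 lists called, from 1099 genes tested. Most lists had fewer than 5 tested members in that fit and were not tested as lists. An estimated correlation left 1 list called of 21. All other alternatives gave 1038 to 1493 genes higher, 1128 to 1729 lower and 17 to 21 lists called, and in none was a called gene called in the opposite direction. Of the other 152 named genes, library totals alone ended the call of 20, leaving out 1 library that of 4 to 13, limma-voom that of 10 (Mup17, Mup15, Slc22a7, Extl1 and Mmd2 among them), glmTreat that of 9 and the replicate block that of 7, and DESeq2 ended none. The replicate numbers did not pair the samples: same-numbered libraries deviated from their group means with correlations of 0.096, -0.034 and 0.045, and not every library correlated best with its own number. With the replicate block 1038 genes were higher and 1128 lower, Fgf21 was at -3.69, Irf3 at 1.28 and Polr2g at 2.66, and 20 lists were called. DESeq2, glmTreat and the robust fit were not run for the lists, which rest on voom values. In the simulation with 3 libraries per group 46.9% of 2-fold changes were recovered, a rate that need not hold for the data.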

Other observations

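The tests of the 3 patterns below were chosen after their results were seen; the count over other splits of the libraries was planned. The interferon-stimulated genes did not move alike, and 3 members were named after their values were seen. Mx1 had a log2 fold change of 0.62 (SE 0.89) and was not called by edgeR, while Cmpk2 and Ifit2 rose with log2 fold changes of 6.37 (SE 0.27) and 5.03 (SE 0.34). Of 26 acute phase genes, 3 were called higher and 8 lower (4 and 8 when adjusted over the list alone), with Hp, haptoglobin, up 2.01-fold and Steap4 up 2.94-fold, while Itih4 fell 3.31-fold and Saa4 fell 3.15-fold; the list was not called (camera adjusted p = 0.214, but 0.0476 with library totals alone, where 8 were higher and 4 lower). Of 22 secreted hepatokines, 4 were called higher and 8 lower (5 and 12 when adjusted over the list alone; camera adjusted p = 0.0396, and adjusted p = 0.312 with an estimated correlation), a list call lost without Ctrl replicate 2 (adjusted p = 0.072) or IRF3-2D replicate 2 (0.068) and with a mean count of at least 50 (0.239); with library totals alone 8 were higher and 5 lower. Igf1 fell 2.55-fold and Enho fell 4.96-fold, while Fst rose 3.76-fold. Of 23 genes of bile acid synthesis and transport, 2 were called higher and 10 lower (4 and 12 when adjusted over the list alone). Among the lower ones was the bile salt export pump gene Abcb11 (2.57-fold). Camera gave the list an adjusted p = 0.0203, and adjusted p = 0.592 with an estimated correlation, and fry gave 0.058. The call was lost without Ctrl replicate 2 (adjusted p = 0.0811). The median of -0.43 became 0.02 with library totals alone, where 7 were higher and 5 lower. Camera still called the bile acid and hepatokine lists down there (adjusted p = 0.01 and 0.0158).

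Several of the following groups went both ways, and camera called none of those it tested as lists with all libraries and TMM scaling. Of 22 cholesterol synthesis genes, 6 were higher and 4 lower (6 and 5 when adjusted over the list alone, 3 and 4 with RLE or upper-quartile scaling, 8 and 2 with library totals alone; camera adjusted p = 0.819), Mvd at 2.30-fold higher and Stard4 at 2.89-fold lower. Of 34 xenobiotic metabolism genes, 6 were higher and 12 lower (9 and 16 when adjusted over the list alone; camera adjusted p = 0.152, but 0.0096 with library totals alone, where 13 were higher and 9 lower), Tiparp at 3.98-fold higher and Cyp3a11, with 15.7% of its words shared with other genes, at 2.97-fold lower. Of 27 lipoprotein genes, 5 were higher and 8 lower (6 and 10 when adjusted over the list alone, 9 and 1 with library totals alone; camera adjusted p = 0.139), Apob at 2.29-fold lower. Of 32 liver transcription factors and nuclear receptors, 5 were higher and 7 lower (6 and 10 when adjusted over the list alone, 14 and 2 with library totals alone; camera adjusted p = 0.158), the coactivator gene Ppargc1a at 2.22-fold higher and Rxra at 7.35-fold lower. Of 17 ATF4 and integrated stress response genes, 2 were higher and 3 lower (2 and 3 when adjusted over the list alone, 6 and 3 with library totals alone; camera adjusted p = 0.462), Gdf15 at 2.68-fold higher and Trib3 at 3.31-fold lower. Of 19 immediate early genes, 5 were higher and 2 lower (5 and 2 when adjusted over the list alone, 8 and 0 with library totals alone; camera adjusted p = 0.618), Btg2 at 2.93-fold higher. Of 18 cell cycle genes, 2 were higher, Ccne1 (8.48-fold) and Pcna (1.68-fold, with 23.3% of its words shared), and 1 lower, Ccnd1 (2.94-fold), and the same numbers held when adjusted over the list alone (5 higher and 1 lower with library totals alone; camera adjusted p = 0.139, but 0.0227 without IRF3-2D replicate 3). Of 15 circadian clock genes, 4 were lower, Tef at 3.30-fold among them, and none higher (5 lower and 2 higher when adjusted over the list alone, 2 lower and 4 higher with library totals alone). Camera did not call this list (adjusted p = 0.162), while fry called it down (adjusted p = 0.0267). None of 10 heat shock genes was called by edgeR, DESeq2 or limma-voom, nor over the list alone (camera adjusted p = 0.473), and 1 passed an unadjusted p of 0.05, Hspa1a, which shares 65.4% of its words with other genes and stood at a log2 fold change of -0.64 (SE 0.26); 5 were higher with library totals alone, and 1 was lower with the replicate block, without Ctrl replicate 1 and among genes with 1 annotated transcript. The Y-linked Eif2s3y stood at 77.7 ± 8.89 CPM in Ctrl and 93.6 ± 8.47 in IRF3-2D (SD, n = 3 each), and none of the 3 tested sex chromosome genes was called by edgeR, DESeq2 or limma-voom, although 1, Eif2s3y, passed an unadjusted p of 0.05 and 2 were higher with library totals alone and 1 without Ctrl replicate 2. A list of nuclear-retained RNAs had no row and was not analysed here.

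The real grouping of the libraries gave 2844 called genes, and the highest of the other 9 splits gave 0. It was the only 1 of the 10 splits with as many genes, and 10 splits are too few for a share under 0.05.

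Genes that every cell uses were listed at low counts. Of 112 ribosomal protein, oxidative phosphorylation and RNA polymerase II genes, 15 had a mean count under 50, Uqcrc1 among them, named after its value was seen. Reads lost to pseudogenes or paralogs may not account for it alone: of 43 such genes that share under 5% of their 31-base words with other genes, 16.3% had a mean count under 50 (exact 95% interval 6.81% to 30.7%). Counts that cover only part of each gene's transcripts remain open. Of genes with 5 or more annotated transcripts 11 of 62 were low, and of those with fewer 4 of 50 (Fisher's exact test, 2-sided p = 0.168). This split cannot decide the question, since a gene with 2 to 4 transcripts can be affected as well. None of the genes with 1 annotated transcript was low, with mean counts of 468 to 3303, but such genes were few. No biological explanation was tested, since the pattern is shared by both groups.

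All 13 mitochondrially encoded genes and 10 of 18 hepatocyte markers were called lower in IRF3-2D liver. TMM scaling alone is unlikely to be the source for the mitochondrial genes, since 11 of the 13 were called lower with library totals alone. For the hepatocyte markers scaling stays open as a source of the calls of single genes. With library totals alone 5 of the 18 were called lower, against 10 with TMM, and their median log2 fold change went from -0.42 to 0.03. The median of all tested genes was then 0.49, and camera still called the list lower than other genes (adjusted p = 0.00264). Fewer hepatocytes among the cells would raise the markers of all other cells alike. Macrophage markers had a median log2 fold change of 0.52 and endothelial markers one of -0.41 (permutation test of the difference, 100000 resamples, 2-sided p = 0.00016). Scaling does not alter this difference, and the endothelial median was close to that of the hepatocyte markers. The permutation test treats genes as independent replicates, which they are not: estimated correlations within the macrophage and endothelial lists were 0.53 and 0.421. With an estimated correlation camera called neither list (adjusted p = 0.592 for each). The test therefore cannot decide, and fewer hepatocytes stay open as a source. A change in the macrophages themselves and an effect of IRF3 in hepatocytes stay open, untested.

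Of 32 tested sex-biased liver genes 13 were called lower, 1 Mup gene among them, and 2 higher. Of 11 tested female-biased genes 7 were called lower and 1 higher (7 and 1 when adjusted over the list alone; camera adjusted p = 0.0098, and adjusted p = 0.337 with an estimated correlation and 0.126 with a mean count of at least 50), and of 21 male-biased genes 6 and 1 (8 and 2 when adjusted over the list alone; camera adjusted p = 0.0467, and adjusted p = 0.691 with an estimated correlation and 0.212 with fry), the latter lost without Ctrl replicate 2 (0.183) or IRF3-2D replicate 2 (0.0911) and with RLE scaling (0.0522), the replicate block (0.0582) or a mean count of at least 50 (0.0743); with library totals alone 7 male-biased genes were higher and 6 lower. Reads shared between paralogs and a single Ctrl library are unlikely sources of the whole pattern: 8 of the 13 lower genes, such as Elovl3 (6.94-fold) and Tox (7.78-fold), share under 5% of their 31-base words with other genes, and at least 11 sex-biased genes were called lower without any 1 Ctrl library. Lower growth hormone signalling through STAT5, a candidate explanation, stays open: of 4 targets written down after the data were seen, 2 were called lower, Igf1 and Igfals, the latter named outside the rule like Socs2 and Cish (log2 fold changes of -1.35 and -1.31), and Socs2 and Cish stood at -1.11 (SE 0.82) and -0.59 (SE 0.50).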
